A study of Homo sapiens with 4 samples.

How the data were processed

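CTCF ChIP-seq was labelled as done in MDA-MB-435 cells, in 4 samples. The 2 asynchronous samples used a rabbit anti-CTCF antibody. The 2 mitotic samples came from cells arrested by 24 h in thymidine (2 mM), released for 3 h, arrested again by 16 h in nocodazole (100 ng/mL) and shaken off the plate, with an antibody against pT431 CTCF. The 1 deposited file used was the peak list of asynchronous replicate 1, and the other 3 samples were not analysed here. Each peak belongs to that library alone and replicates were not pooled, per the file headers.

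Bowtie2, HOMER and the build hg38 are named in the submitters' processing notes, and their versions are not given in the sources used here. Per the file headers, findPeaks was run in its factor style with no control library named, a fragment length of 164 bp, at most 1 tag per position, a false discovery rate of 0.001 (15 tags), at least 4-fold over the surrounding 10 kb and a local Poisson p of 1e-04. Of 45053 putative peaks, 2591 were removed by the local filter and 0 as too clonal, per the file headers. A peak list without a control library can hold regions of extra DNA copies or of repeats, and a list of called peaks gives no level where no peak was called.

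The deposited tag signal is the tag count per peak scaled to 10000000 tags, per the file headers. The deposited focus ratio is a fraction of tags on the expected side of the peak centre, computed by the authors' peak caller. The deposited peak score is the caller's own score. The deposited fold over the local region is a ratio of tag densities, and the clonal fold is a ratio of tags per distinct position to the expected value, as the authors' caller gave it. The deposited p-value against the local region was made by the authors' caller and was 0 for 191 peaks, and was not used to test anything here. Local background was computed here as the normalized tags divided by the fold over the local region. Depth was 19210460 tags, and tags per peak gave exact Poisson 95% intervals.

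Gene names, kinds and positions came from a RefSeq table of the assembly GRCh38.p14, whose chromosomes are those of hg38. Genes on chromosomes 1 to 22 and X were kept, 58414 in all and 19821 protein-coding. The table gives neither strand, exons nor sequence. The planned motif, motif orientation, exon and untranslated region results were therefore not computed. Either annotated gene end replaced the transcription start site, and gene length in 20 bins replaced promoter GC for matching random lists, a change made after the table and the peak list had been seen. Assembly gaps were replaced by stretches of at least 1 Mb with neither a gene nor a peak.

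Random positions kept each chromosome's peak number (1000 placements, 200 for neighbours and distances). Gene lists and clusters were fixed before the data were examined. Lists were compared with 10000 random lists and clusters, with 10 kb added on each side, with 10000 random windows of which at most 10% was blank. Ties were split evenly. Percentiles under 2.5 or over 97.5 were taken to stand apart, as a description of this library. No p-value across genes is given. Of 26 imprinted genes asked for, 23 were found among protein-coding genes. H19, MEG3 and KCNQ1OT1, which are RNA genes, were left out of that list. Shares have Clopper-Pearson 95% intervals. Relations across autosomes have permutation tests with 100000 resamples and Benjamini-Hochberg adjustment over 3 relations.

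Genes were named by a rule fixed before the data were examined: the nearest protein-coding gene of the 10 peaks of highest score, up to 3 members per list with the highest-scoring peak and the alphabetically first member without one, each cluster's peak count, and CTCF, MYC and H19. Some genes that the rule selects are not reported here. Alternatives varied the score threshold, the window, the gene set, the background and peak merging. Added after seeing the data were circular shifts of lists, peaks moved by 20 to 200 kb, ties counted against standing apart, and counts without CTCF, RAD21, STAG3, REC8 and RAD21P1.

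The list comparison was tested on simulated peaks over 19821 genes. With 40% of 200 listed genes given a peak, 43.0% were recovered at percentile 100 against 23.2% of all genes. With 20% given a peak the percentile was 52.9, where 22.8% of all genes had one. Of 200 random lists of 50 genes on the real peaks, 5 fell outside the percentiles. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.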

Results

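CTCF, the zinc finger protein that binds insulators and loop anchors, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MDA-MB-435, an established human melanoma cell line. The series held 4 samples in 2 groups. The first group was 2 replicates of asynchronous cells with an antibody against CTCF, and the second was 2 replicates of mitotic cells with an antibody against CTCF phosphorylated at pT431. Only the peak list of asynchronous replicate 1 was analysed, so the asynchronous and mitotic groups were not compared here, and no value below has a replicate check. That library held 19210460 tags, of which 11.66% lay in peaks. All intervals cover counting error only.

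The peak caller reported 42462 CTCF peaks, all of the same width, of which 42388 lay on chromosomes 1 to 22 and X. Tag counts per peak are given as normalised tags, the number expected in a library of 10000000 tags. The median peak held 38 tags, or 20 normalised tags with a 95% Poisson interval of 14.0 to 27.2. At the 90th percentile of peaks the value was 55.2 normalised tags (45.2 to 66.7), so strong peaks were measured more precisely than the median one. The authors' scores, folds and focus ratios are used below only to describe and rank peaks within this list. The median fold over the surrounding 10 kb was 13.6. Neighbouring peaks lay a median of 35.1 kb apart. A neighbour within 20 kb was found for 55.1% of peaks (54.6 to 55.5), against a mean of 45.9% and at most 46.6% in 200 random placements.

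Of the 10 peaks with the highest score, 3 lay in or beside the CTCF gene itself and REC8, which encodes the meiotic cohesin subunit. The highest score belonged to a peak on chromosome 3 (93470428 to 93470776, hg38) with 3062.7 normalised tags, whose nearest protein-coding gene, PROS1, was 402 kb away. A peak inside CTCF (chromosome 16, 67611284 to 67611632) held 700.9 normalised tags (664 to 739), and a peak 471 bp from the end of CTCF held 247.8 (226 to 271). The peak inside REC8 (chromosome 14, 24172854 to 24173202) held 1183.2 (1135 to 1233). Its score was 378, below the 389.5 of the COMTD1 peak, which held 300.6 normalised tags. The normalised tag counts, at REC8 and at the other peaks alike, were not held to 1 tag per position. Repeated tags can therefore make their intervals too narrow. The peak at CLPB, a mitochondrial chaperone gene, had a focus ratio of 0.897 and held 354.2 normalised tags, 223 bp from the gene's end. The peak 122 bp from COMTD1 held 300.6 normalised tags and stood 102-fold over its surroundings. The peak 24 bp from the end of STAG1, which encodes a cohesin subunit, held 259.8 normalised tags (237 to 284) and stood 55.6-fold over its surroundings. The remaining 3 of the 10 were nearest to SHCBP1 at 188 kb, inside LOC124907874, and nearest to ENAH at 11.7 kb. The SHCBP1 peak lay within 1 Mb of a peak-free stretch of at least 2 Mb. With no control library named, repeats or extra DNA copies cannot be told from binding there or at the chromosome 3 peak of highest score.

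The cohesin and CTCF genes REC8, CTCF, STAG3 and RAD21 held peaks on a raised local background. REC8 held 3 peaks, CTCF 8 and the further peak 471 bp outside it, STAG3 9 and RAD21 7. Among 2849 protein-coding genes with at least 3 peaks, these were ranks 1 to 4 by the ratio of the highest local background within the gene and 1 kb around it to the median at the nearest 6 peaks farther out. The ratio was 62.9 for REC8, 16.3 for CTCF, 14.1 for RAD21 and 13.6 for STAG3, against a median of 1.36 over all 2849 genes and 8.31 for the next gene, NRG1. RAD21 encodes the kleisin subunit of mitotic cohesin, and STAG3 a meiotic cohesin subunit. The ranking used each gene's single highest value. The median local background of the same peaks was 118.8 in REC8, 9.27 in CTCF, 8.39 in RAD21 and 3.20 in STAG3. The STAG3 median lay within the 1.22 to 5.06 of its outside peaks. ACBD4 (17.5) and BCL6 (10.8) had higher medians than CTCF, RAD21 and STAG3. All these values, for REC8 and for the other genes, rest on tag counts not held to 1 tag per position. REC8, CTCF, STAG3 and RAD21 were singled out after their values were seen.

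**Figure D1:**
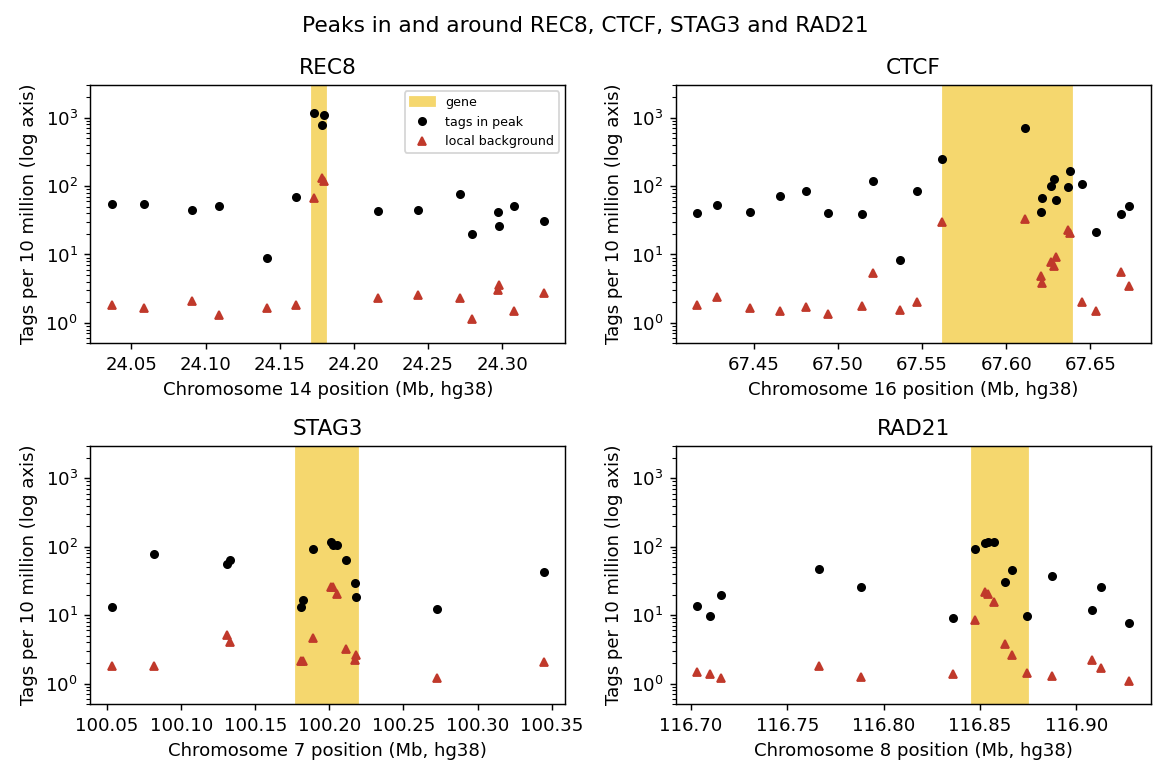
Normalised tags in each CTCF peak (black circles) and the local background around it (red triangles), on a log axis, by hg38 position in and around REC8, CTCF, STAG3 and RAD21 (gene spans shaded). Local background reached 129 in REC8, 33.1 in CTCF, 26.0 in STAG3 and 21.7 in RAD21, and the nearest 6 peaks outside each gene had medians of 1.54 to 2.05.

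CTCF peaks were concentrated at the ends of protein-coding genes. A share of 12.4% of peaks (5251 of 42388, Clopper-Pearson 95% interval 12.1 to 12.7) lay within 1 kb of an annotated gene end, against a mean of 2.75% and at most 3.03% in 1000 random placements on the same chromosomes. Within 250 bp of a gene end, peaks were 8.20 times as frequent as random positions. Peaks inside genes but over 1 kb from their ends made up 41.9%, against 43.6% of random positions, and peaks outside genes 45.7%, against 53.7%. At distances over 100 kb from any gene end, peaks were 0.529 times as frequent as random positions. Gene ends stand here for transcription start sites, because strand and transcript structure were not used here. With each peak moved by 20 to 200 kb instead, an alternative chosen after seeing the data, the random share was 3.96%.

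The share of peaks at gene ends was highest among the strongest peaks and lowest in the middle of the score range. In the top score decile 26.4% of peaks lay within 1 kb of a gene end (25.1 to 27.8), in the sixth decile 8.14% (7.33 to 9.003) and in the lowest decile 14.4% (13.3 to 15.5). The intervals of these 3 deciles did not overlap. The median focus ratio, the fraction of tags on the expected side of the peak centre, rose from 0.763 in the lowest decile to 0.898 in the highest.

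**Figure D2:**
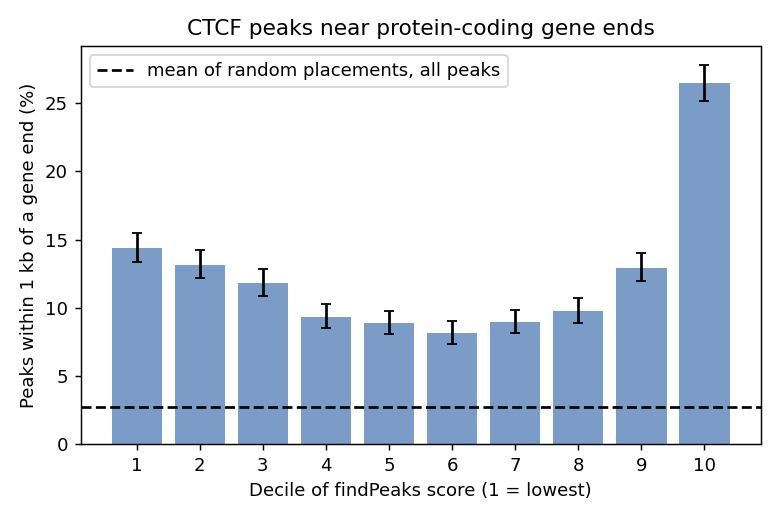
Percent of CTCF peaks whose centre lay within 1 kb of a protein-coding gene end, by decile of the peak score, with 95% Clopper-Pearson intervals. The top decile reached 26.4% and the sixth 8.14%, and the dashed line marks the mean of random placements of all peaks, 2.75%.

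Of 19821 protein-coding genes, 5635 (28.4%, 27.8 to 29.1) had a CTCF peak within 1 kb of an end. Gene lists were then set against 10000 random lists of the same size and gene length. Of 16 lists, 5 had a higher percentile than the central 95% of random lists, 5 a lower one and 6 lay within, with ties split evenly, where chance alone would put 0.8 lists outside. The histone and liver lists lay exactly on a bound, and with ties counted against standing apart, an alternative chosen after seeing the data, 4 lists were higher and 4 lower.

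Clustered protocadherins, the cell surface proteins of neuronal identity encoded in tandem on chromosome 5, had the highest share: 43 of 53 genes (81.1%, 68.0 to 90.6, percentile 100). Many of these genes share an annotated end, so 1 peak there counts for several genes, and 36 of 53 had a peak at the lower-coordinate end. PCDHGB7 had a peak of 53.4 normalised tags (43.8 to 65.0) 48 bp from its end, and PCDHA1 had none. CTCF and cohesin machinery genes followed with 13 of 19 (68.4%, percentile 99.95). Besides CTCF and STAG1, PDS5A, a cohesin regulator, had a peak of 105.7 normalised tags 97 bp from its end, and ESCO2 had none. CTCF and RAD21 belong to this list and carry the raised background described above, and without peaks at those loci 11 of 19 genes had a peak (percentile 99.3). Housekeeping genes had a peak in 11 of 20 (55.0%, percentile 99.4), with 82.2 normalised tags at ACTB, the beta-actin gene, 86.4 at RPLP0 and 57.8 at SDHA, and none at ALDOA. Their percentile was 94.6 with a window of 500 bp and 97.4 with 5 kb, both within the random range. Cytosolic ribosomal protein genes had a peak in 35 of 85 (41.2%, percentile 99.9), among them RPL26 at 127.3 and RPL36 at 120.8 normalised tags, and FAU had none. Replication-dependent histone genes had a peak in 15 of 69 (21.7%, percentile 98.1), led by H4C2 at 49.5, H2BC26 at 46.1 and H2AC21 at 31.2 normalised tags, and H1-1 had none. The histone percentile was 88.2 with a window of 500 bp, and on the other side of the median against random lists not matched on length (11.1), at or above the median score (17.7) and with circular shifts along the gene order, chosen after seeing the data (19.1).

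Olfactory receptor genes had a peak in 15 of 387 (3.88%, 2.19 to 6.31, percentile 0), against a mean of 20.02% in random lists. OR2L13 had the strongest at 134.8 normalised tags, then OR52K1 at 52.6 and OR2V2 at 50.0, and OR10A2 had none. Keratin-associated protein genes had a peak in 2 of 94 (2.13%, percentile 0.020), at KRTAP5-5 with 66.1 normalised tags and KRTAP10-7 with 10.4, and none at KRTAP1-1. Melanocyte lineage genes had a peak in 2 of 24 (8.33%, 1.03 to 27.0, percentile 0.780), at KIT, the receptor for stem cell factor, with 15.9 normalised tags and at DCT, an enzyme of melanin synthesis, with 13.3. CDH19 had none, and neither did any other member within 1 kb. With a window of 5 kb the melanocyte percentile was 9.62. Liver-restricted genes had a peak in 2 of 22 (9.09%, percentile 2.14), at APOA1 with 53.6 normalised tags and at TAT, and none at AHSG. The liver percentile was 53.0 with a window of 5 kb, 2.9 with 500 bp and 7.1 at or above the median score. Numbered zinc finger genes had a peak in 126 of 509 (24.8%, 21.1 to 28.7, percentile 0.905), led by a shared peak at ZNF398 and ZNF425 of 130.4 normalised tags and by ZNF653 at 114.0, and none at ZNF10. The zinc finger percentile lay within the random range with a window of 500 bp (18.0), against random lists not matched on length (3.1) and with circular shifts along the gene order, chosen after seeing the data (8.54).

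The 6 lists within the random range were HOX genes with 14 of 39, imprinted genes with 7 of 23, melanoma and growth control genes with 8 of 22, mitotic genes with 8 of 32, mammary epithelial genes with 5 of 22 and neuronal genes with 4 of 22. Their percentiles were 91.4, 60.2, 73.6, 30.5, 30.5 and 12.6. Among HOX genes, which pattern the body axis, HOXC10 had 54.1 normalised tags, HOXD13 48.7 and HOXB13 47.9, and HOXA11 had no peak. With a window of 5 kb, 31 of 39 HOX genes had a peak and the percentile was 100. HOX genes lie in clusters on 4 chromosomes, so 1 peak can then count for several of them, and the random lists were not matched on that. Of the imprinted genes, a single peak of 58.3 normalised tags lay at the adjoining ends of PEG10 and SGCE, UBE3A had 40.9, and CDKN1C had none. In the growth control list, ARID2 had 99.2 normalised tags and MAP2K1 57.5, and CCND1 had none. Mitotic genes were led by CDC20 at 21.9, PLK1 at 18.7 and ESPL1 at 16.4 normalised tags, and AURKA had none. Counting only peaks at or above the median score, 1 mitotic gene remained and the percentile was 1.34. MUC1 had 96.8, ELF5 31.2 and FOXA1 29.2 normalised tags in the mammary epithelial list, where AGR2 had none. In the neuronal list MAP2 had 110.9, GAD1 18.7 and NEFL 16.9, and CAMK2A had none.

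**Figure D3:**
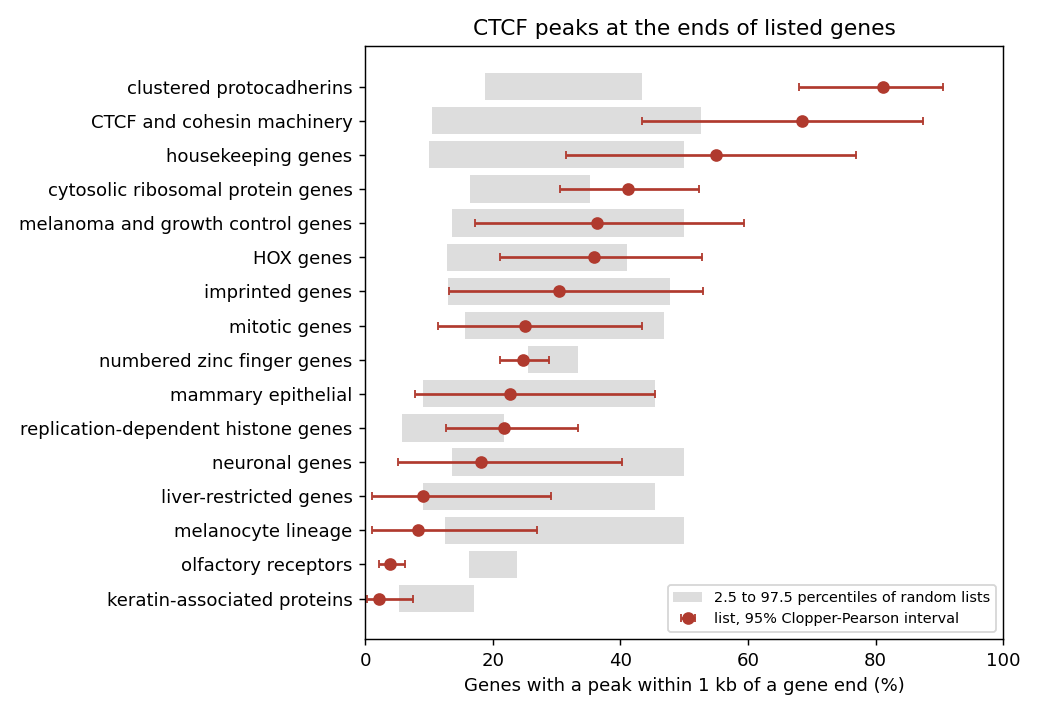
Percent of each list's genes with a CTCF peak within 1 kb of a gene end (red points, 95% Clopper-Pearson intervals) beside the central 95% of 10000 random lists matched on gene length (grey bars). Clustered protocadherins reached 81.1% and olfactory receptors 3.88%.

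Peak density was then measured over 25 gene clusters and loci. In 6 of them the percentile of the density lay above the central 95% of 10000 random windows of the same length on the same chromosome, with ties split evenly. In 19 it lay within the range and in 0 below it. Chance alone would put 1.25 outside if each region could fall on either side. However, only the protocadherin, SNRPN-UBE3A, type I keratin, type II keratin, HLA class II and epidermal differentiation regions could fall below. Elsewhere too many random windows held 0 peaks, so the lack of low regions says little. The random windows were not matched on gene content either. Peaks were concentrated at gene ends, so a region rich in genes can exceed such windows on that count alone, which was not tested. The protocadherin clusters (chromosome 5, 140776140 to 141522975) held 44 peaks, 5.89 per 100 kb (4.28 to 7.91), against a mean of 1.35 in random windows. The HOXD cluster held 8 peaks (6.48 per 100 kb, percentile 99.7) and the HOXA cluster 7 (5.51, percentile 98.6). The HOXB cluster held 10 peaks (percentile 90.8) and the HOXC cluster 6 (percentile 94.7), both within the range, though the HOXB cluster was above it with windows from all chromosomes (percentile 97.7). The MYC locus, home of a growth-promoting transcription factor, held 4 peaks (14.5 per 100 kb, 3.96 to 37.2, percentile 99.9). The imprinted GNAS locus held 6 peaks (percentile 98.1) and the growth hormone cluster 4 (percentile 98.1), both equal to the upper bound of random windows, so that 4 of the 6 stood apart with ties counted against it. Counting only peaks at or above the median score left 3 of these 6 outside the range, and the protocadherin clusters were then at percentile 93.5, GNAS at 60.9 and the growth hormone cluster at 90.8.

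The other regions lay within the random range. The type I interferon cluster held 16 peaks, the type II keratin cluster 27, the type I keratin cluster 11, the HLA class II region 20 and the epidermal differentiation complex 50. The KCNQ1-CDKN1C region held 6 peaks, MITF 4, IGF2-H19 3, SNRPN-UBE3A 3, APOA1-APOA5 3 and SOX10 2. The alpha-globin, albumin and DLK1-MEG3 regions held 1 peak each. The beta-globin, CDKN2A-CDKN2B and TYR regions held 0 peaks, at percentiles 20.5, 23.9 and 10.9 of random windows. These are the lowest they could reach, since 41.05%, 47.9% and 21.7% of random windows also held 0 peaks, so a depletion could not be called. H19, an imprinted RNA gene on chromosome 11 (1995176 to 2001266), lay in a stretch of 206 kb without a called peak. MYC (chromosome 8, 127735434 to 127742951) had a peak of 23.7 normalised tags 787 bp inside its lower end.

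**Figure D4:**
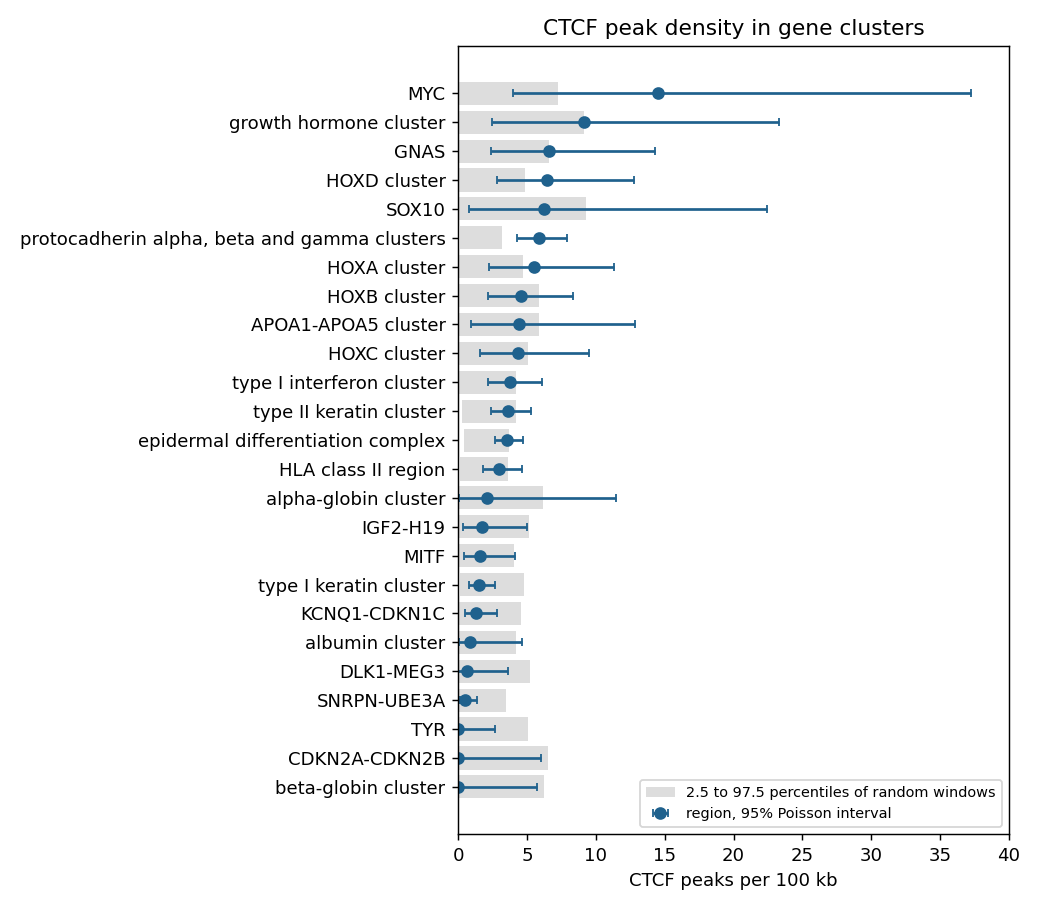
CTCF peaks per 100 kb in 25 regions (blue points, 95% exact Poisson intervals) beside the central 95% of random windows on the same chromosome (grey bars). MYC reached 14.5 and the protocadherin clusters 5.89 peaks per 100 kb.

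Chromosomes rich in genes were rich in CTCF peaks. Among the autosomes, density ran from 11.05 peaks per Mb on chromosome 21 to 26.7 on chromosome 19, and across these 22 chromosomes it rose with protein-coding genes per Mb (Spearman's rho 0.90, permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 1.5e-05; Pearson's r 0.93, permutation p = 1e-05, adjusted p = 1.5e-05). Without chromosomes 17 and 19, the farthest from the median gene density, r was 0.87. The local background also rose with gene density (rho 0.79, permutation p = 4e-05, adjusted p = 4e-05; r 0.74, permutation p = 2e-05, adjusted p = 2e-05; r 0.61 without chromosomes 17 and 19), and peak density rose with local background (rho 0.88 and r 0.84, permutation p = 1e-05 and adjusted p = 1.5e-05 for both; r 0.92 without chromosomes 3 and 19). These 3 relations formed the family, the latter 2 were chosen after seeing the data, and all tests were two-sided. Chromosomes of one library are not independent replicates. Local background was known only at called peaks, and the surrounding 10 kb can hold tags of neighbouring peaks. Its relation to peak density can therefore arise in part by construction.

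Chromosome X had 7.12 peaks per Mb (6.70 to 7.56), a median local background of 0.743 normalised tags and a median of 13.5 tags per peak, against 15.3, 1.49 and 20.3 on the autosomes. The median fold over the local region went the other way, 19.03 on X against 13.45 on the autosomes. On chromosome 3 the local background changed along the chromosome. Peaks within 50 kb of a gene end placed the largest step between positions 109369673 and 111080525. At peaks more remote from genes, which were not used to place it, the median rose from 1.23 before the step (597 peaks) to 1.76 after it (549 peaks), a ratio of 1.43 (bootstrap 95% interval 1.39 to 1.49).

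**Figure D5:**
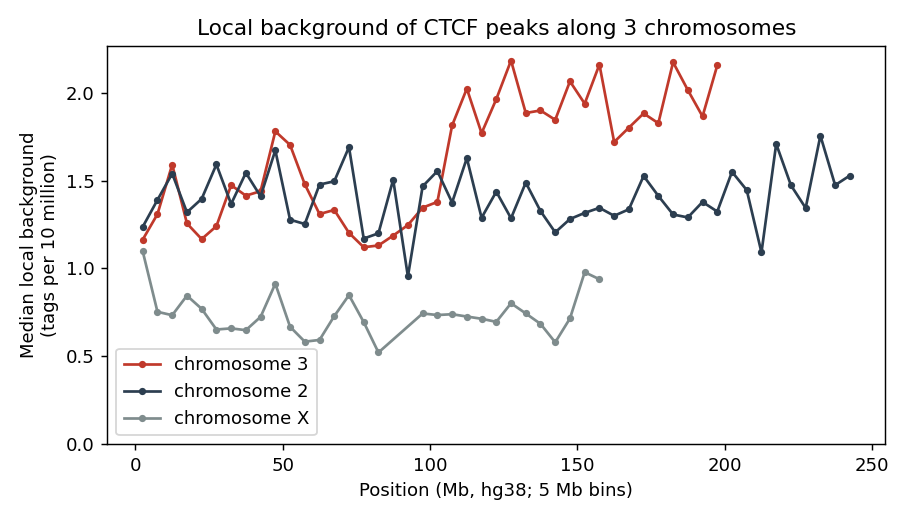
Median local background of CTCF peaks, in normalised tags, in 5 Mb bins along chromosomes 2, 3 and X by hg38 position. Chromosome 3 is higher from the bin that holds 109 Mb (1.81, against 1.38 in the bin before). Most of that bin lies before the step used, so the binned medians rise earlier than that step. Remote peaks had a median of 1.76 after the step used, against 1.23 before it. Chromosome X lies lowest with a median of 0.743.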

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

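All tests in this part were chosen after the results were seen. Signal outside the report's comparisons was found at 2 places. The RAD21 pseudogene RAD21P1 on chromosome X (100801112 to 100803259) held 2 peaks, with 190.0 and 171.0 normalised tags, and unplaced or unlocalised sequences held 37 peaks. Of 15067 pseudogenes of up to 5 kb, 196 held a peak and 2 held at least 2 peaks, RAD21P1 and DOC2GP.

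The raised tags in REC8, CTCF, STAG3 and RAD21 were weighed against 3 explanations. Extra copies of a whole genomic region would also raise the nearest peaks. However, the median over the nearest 6 peaks more than 1 kb outside each gene was at most 1.40 times the chromosome's median. The lowest inside-to-outside ratio, taken at each gene's highest background, was 13.6. Single strong CTCF sites stay open: against 10000 draws matched on score, the median focus ratio of the 27 peaks inside was 0.871 (percentile 4.01), and their median fold over the local region was 8.08, below each draw (20.5 to 46.1), but the genes were picked on the local background computed from that fold. Next, called neighbours were taken off the background, and each gene's peak of highest background and those within 10 kb of it were left out. The fold of the other 14 peaks was then at percentile 0.17 pooled. That value excluded single strong sites until the rule was changed, once it had been seen, to ask for each gene. CTCF was at 92.2, RAD21 at 13.1, STAG3 at 2.63, and REC8 had 0 such peaks. Taking neighbours off raises the fold whatever made those neighbours. At 1 CTCF peak it rose from 12.7 to 101.6, at another from 8.08 to 9.71. The CTCF percentile is therefore not evidence for single strong sites. A candidate explanation for RAD21 is intron-free DNA copies of that gene in the library, since such reads would also align to RAD21P1. The lowest local background in RAD21P1 was 24.3 times the median of chromosome X. However, its 2 peaks lay so close together (100801168 to 100802277) that the surrounding 10 kb of each held tags of the other. Those tags add to that background, so the ratio is limited support. For CTCF, REC8 and STAG3 intron-free copies were not tested, and exon positions were not used here.

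The higher local background on the distal part of chromosome 3 was weighed against extra copies of that part and stronger binding relative to background. Extra copies may account for the pattern: at remote peaks the background ratio after over before the step was 1.43. The ratio of tags was 1.30 (bootstrap 95% interval 1.12 to 1.46). The same procedure on the 15 other chromosomes with at least 50 remote peaks on each side gave background ratios of 0.766 to 1.27. The 0.766 (0.704 to 0.812) belonged to chromosome 5, where the background fell from 1.61 to 1.23. That fall was a larger change than the rise of 1.27, though smaller than the rise on chromosome 3. The fold over the local region had a ratio of 0.827 (0.742 to 0.904), and the other chromosomes ranged from 0.697 to 1.40. Stronger binding would raise the fold, but with so wide a range it stays open too. For extra copies the fold cannot decide, since they would also let weaker sites pass the fixed threshold of 15 tags. Chromosome X, with 0.50 times the autosomal background, had 1.41 times the autosomal median fold. The fold was first judged by its bootstrap interval alone and the position first set at the centromeric peak-free stretch, and both were changed once the values had been seen. No copy number measurement was used here, so this stays a hypothesis.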

How the results depend on the processing

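The added alternatives (5 loci left out, moved peaks, circular shifts, ties) and gene length matching, which replaced the planned matching, were chosen after seeing the data. No paired analysis was possible because only 1 of the 4 samples was analysed and no result compares groups. The planned motif and motif orientation alternatives, and matching on promoter GC, were not run because no sequence was used here.

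The share of peaks at gene ends exceeded random placement under each of the 7 alternatives run. It was 13.2% for peaks at or above the median score and 13.2% for whole intervals, 8.92% within 500 bp, 25.9% within 5 kb and 18.6% for ends of all genes, where the definition of the window or gene set itself moves the share. Peaks at or above the median score numbered 21275 by construction. Of the 10 lists outside the random range, 8 kept their side without length matching, 6 with 500 bp (3 higher and 3 lower), 7 with 5 kb (5 higher and 3 lower in all), 8 at or above the median score, 8 with circular shifts, 8 with ties counted against standing apart and 10 without the 5 loci. Replication-dependent histone genes crossed the random median, at percentile 11.1 without matching, 17.7 at or above the median score and 19.1 with circular shifts. Liver-restricted genes crossed it at 53.0 with 5 kb. The cause was not tested. With windows from all chromosomes 7 clusters were above range, the 6 and the HOXB cluster (percentile 97.7, against 90.8). Of the 6, 4 stayed above with ties counted against it and 3 at or above the median score, for which the cause was not tested. Spearman's rho of peak and gene density was 0.92 for peaks at or above the median score. Depth limits weak peaks, since the threshold was 15 tags.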

Other observations

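All tests in this part were chosen after the results were seen. Genes for transfer RNAs carried CTCF peaks often. Within 1 kb of an end, 111 of 424 tRNA genes had a peak (26.2%, 22.1 to 30.6), against a mean of 4.90% and at most 8.49% when each peak was moved by 20 to 200 kb. Among the 319 tRNA genes over 5 kb from any protein-coding gene end, 60 had a peak (18.8%, 14.7 to 23.5), against at most 8.46% with moved peaks. Long non-coding RNA genes had a peak in 14.3%, against 6.60% with moved peaks. Small nucleolar RNA genes had one in 2.94% (2.06 to 4.07), against a mean of 4.08%, and plain pseudogenes in 3.87%, against 4.39%. tRNA genes lie in groups, so neighbouring genes can share a peak.

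CDKN2A and CDKN2B, the cell cycle inhibitor genes on chromosome 9, lay in a stretch of 415 kb without a called peak (21814022 to 22228728), and 25 of the 1771 stretches on that chromosome were at least as long. H19 lay in a stretch of 206 kb, and 103 of 2273 on chromosome 11 were at least as long. A peak list gives no level there. Among the 20 peaks of highest local background outside the 5 loci, 4 lay within 1 Mb of a peak-free stretch of at least 2 Mb, all of them at 1 locus on chromosome 16 (46390465 to 46400938), against 525 of all 42358 peaks outside those loci (1.24%). BCL6 held 5 peaks, 4 of them with a local background between 10.5 and 11.9, and a median focus ratio of 0.863. These 4 peaks lay so close together (187738817 to 187742375) that the surrounding 10 kb of each held tags of the others, which adds to that background.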
